A study of Mus musculus with 12 samples.

How the data were processed

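Transcript levels were measured on 12 Affymetrix expression arrays of TBV2 cells, a wild-type mouse embryonic stem cell line. Per the labels' protocols, the cells were seeded at low density on gelatin without feeder cells and kept for 5 days in medium with leukemia inhibitory factor (LIF), either without addition (control) or with 500 µM L-proline. Total RNA was checked by electrophoresis, converted to biotin-labelled cRNA and hybridized, per the labels' protocols. The sample titles number biological replicates 1 and 2 in each group and add a letter from a to c to each number. What the letters stand for is not given in the labels, so the 3 arrays of one number were taken as repeats of 1 biological replicate and averaged, which left 2 control and 2 proline values per gene. How the biological replicates were kept apart is not given in the labels either. The p-values of single genes therefore measure only the spread between these values, which may be partly technical.

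The deposited table holds log2 signals of 45101 probe sets, which the authors had already normalized across arrays. Per the submitters' processing notes, MAS5 and RMA were used, with no version and without saying which of them made the table. The values themselves ran from 2.10 to 14.8 with no missing value, and the array medians lay between 5.98 and 6.03, as log2 summaries of RMA type have and linear MAS5 signals do not. Detection calls and background levels were not used here, so a low signal cannot be separated from background by these values. For arrays, the number of biological replicates limits the precision.

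Probe sets were named from the platform annotation, with symbols updated by gene ID through a RefSeq gene table of assembly GRCm38.p6, used for names alone. Exactly 1 gene symbol belonged to 34945 probe sets, 932 had several and were not named, 9160 are unnamed here, and 64 are array controls. The update changed 0 symbols, and 204 probe sets whose gene ID was not found kept the annotation's symbol. Each of the 18193 genes was represented by its probe set with the highest mean over the 12 arrays, which is a choice for the 9010 genes with more than 1 probe set. No filter on dim signals was applied.

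Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the 4 means, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors of log2 fold changes are limma's moderated standard errors. The fit had 2 residual and 2.60 prior degrees of freedom. An exact permutation test of 2 values against 2 cannot give a two-sided p under 0.333, so every p here rests on limma's model. A second count took genes changed at least 2-fold. Lists of genes, 25 in number with 505 of their 544 entries measured, were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera was repeated with a correlation estimated for each list from the 12 arrays, with negative estimates set to 0, and fry tested each list by itself. Camera sets list genes against other genes, so its p-values do not measure the spread between biological replicates.

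The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 largest increases and the 8 largest decreases among genes past the threshold whose 6 proline arrays all lay on one side of the 6 control arrays, leaving out clone-type symbols. It also took the 4 members of each list with the smallest p and a short fixed set of pluripotency, mesenchymal and proline metabolism genes. Other list members are given as examples of their list.

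The procedure was tested on simulated data before use, with 18193 genes, the real means and spreads, and 200 changed genes in each of 5 simulations of the comparison of proline with control. It called 20% of genes changed 2-fold, 77.5% of those changed 4-fold and 87.4% of those changed 8-fold, with 3.4 false calls among 123 calls on average. Taking the 12 arrays as independent samples gave 1640 false calls on average in the same simulations. Simulated genes varied independently of each other. In the real data, control 2 minus control 1 correlated with proline 2 minus proline 1 across genes (r = 0.338). The simulated rates of false calls therefore need not hold for the real comparison. Alternatives were quantile normalization, median centring, leaving out genes under the 40th percentile of signal, the median over a gene's probe sets, every probe set by itself, the 12 arrays as independent or with a random block, the replicate number as a block, an intensity trend, a 1.5-fold threshold, and leaving out each biological replicate and each array. Intervals of list medians come from 10000 bootstrap draws of the members and cover the spread over genes alone. Plots were drawn with matplotlib 3.10.9.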

Results

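The data are 12 arrays of TBV2 mouse embryonic stem cells, 6 from control cultures and 6 from cultures given 500 µM L-proline for 5 days in the presence of LIF, the cytokine that keeps these cells pluripotent. Each group holds 2 biological replicates of 3 arrays each. Across probe sets, arrays of the same biological replicate correlated at r = 0.996 to 0.998, those of the other biological replicate of the same group at 0.985 to 0.989, and arrays of different groups at 0.962 to 0.981. The first principal component carried 66.1% of the variance and separated the groups, and the second carried 14.1%. In both groups biological replicate 2 lay further toward the proline side of the first component than biological replicate 1.

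Array control probe sets also differed between the groups, by no more than the larger difference between biological replicates of one group. The 5' minus 3' signal of beta-actin, a measure of RNA integrity and labelling, was -0.70 ± 0.28 in controls and -0.45 ± 0.30 after proline (log2, SD of 2 biological replicates). Poly-A spike-ins, added to the RNA before labelling, read 8.74 ± 0.27 and 8.31 ± 0.37, and hybridization spike-ins 11.13 ± 0.09 and 10.86 ± 0.20. The 18S ribosomal RNA probe sets read 10.39 ± 0.50 in controls and 9.05 ± 0.98 after proline, with 8.35 in proline replicate 2.

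**Figure D1:**
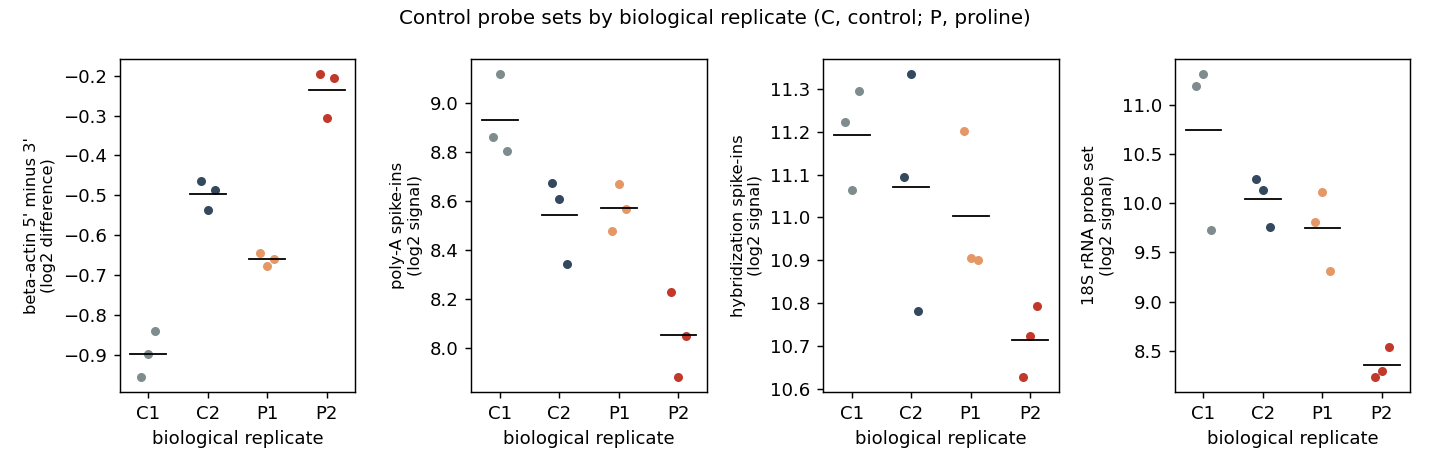
Signals of control probe sets on each of the 12 arrays, in log2 units, by biological replicate (C, control; P, proline; points, arrays; bars, means of 3 arrays). Beta-actin 5' minus 3' was higher and poly-A spike-ins were lower in replicate 2 of each group, and 18S ribosomal RNA ran from 10.74 in control replicate 1 to 8.35 in proline replicate 2.

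The comparison of proline with control asks which transcripts changed when the amino acid was added to cells held in LIF. Fgf5, the standard marker of the post-implantation epiblast, rose by a measured 23.8-fold after proline, from a log2 signal of 4.84 ± 0.61 to 9.41 ± 0.10 (SD, n = 2 biological replicates per group). Fgf8, a signal of the primitive streak, rose by a measured 20.5-fold. Inhbb, which encodes the beta-B subunit of activins and inhibins, fell from 11.31 ± 0.39 to 5.18 ± 0.02, a level under the 40th percentile of probe sets (5.36), so that no exact fold is given. The other probe set of Inhbb fell by 1.86 on the log2 scale. Khdc3, a component of the maternal subcortical complex of the oocyte, fell 13.2-fold. Of 18193 genes, 794 passed an adjusted p of 0.05 in limma, 551 higher and 243 lower after proline, so that 69.4% were higher.

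The other large increases were in the neurofilament gene Nefm (log2 fold change 4.26 ± 0.47, moderated SE), the insulin receptor substrate Irs1 (3.68 ± 0.57), the tight junction gene Cldn7 (3.48 ± 0.41), the neuronal kinesin Kif1a (3.45 ± 0.27), the calcitonin receptor Calcr (3.39 ± 0.29) and Ms4a4d (3.36 ± 0.22). The other large decreases were in the organic cation exporter Slc47a1 (-2.83 ± 0.45), Calml4 (-2.80 ± 0.27), the myosin gene Myo1f (-2.77 ± 0.24), Accsl (-2.75 ± 0.32), the myoblast fusion gene Mymx (-2.73 ± 0.39) and the trypsin inhibitor Spink1 (-2.69 ± 0.23). Adjusted p for these 16 genes lay between 0.0207 for Inhbb and 0.0485 for Slc47a1. That their 6 proline arrays lay on one side of the 6 control arrays was a condition of their choice. Of the 794 genes past the threshold, 793 met it. Of the 794 genes, 619 changed at least 2-fold, 431 higher and 188 lower. Control signals of 110 of the higher genes lay under the 40th percentile of probe sets. Fgf5, Fgf8, Calcr and Ms4a4d were among them, and so were Cdh2, Twist1, Zfp521 and Fabp7, given below. Proline signals of 31 of the lower genes, Inhbb and Myo1f among them, also lay under it. At such levels signal is not separated from background, and a measured fold is not exact. For 28 named genes past the threshold with more than 1 probe set, all probe sets of a gene measured in one direction. In 16 of them the weakest lay below the one used by over 1.5 times: Inhbb, Fgf5 (3.003), Sox3 (0.78), Zyx (0.63), Axin2 (0.61), Zfp521 (0.56), Acvr2b (0.48), Tpm2 (0.47), Msx1 (0.32), Nkd2 (0.06), Myo1f (-1.23), Nid1 (-1.14), Pfkp (-1.02), Lifr (-0.93), Tet1 (-0.59) and Nr5a2 (-0.48). The smallest adjusted p of any gene was 0.0207 and the count of 794 depends on the unit tested, with 351 genes past the threshold by the median over probe sets and 45 probe sets when each was tested by itself. It was 3987, 58.1% of them higher, with the 12 arrays in a random block and 6804, 52.5% higher, with the 12 arrays taken as independent. Leaving out control replicate 1, control replicate 2, proline replicate 1 or proline replicate 2 left 0 genes past the threshold in limma, with 2766, 3544, 3676 and 2890 genes at an unadjusted p under 0.05.

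**Figure D2:**
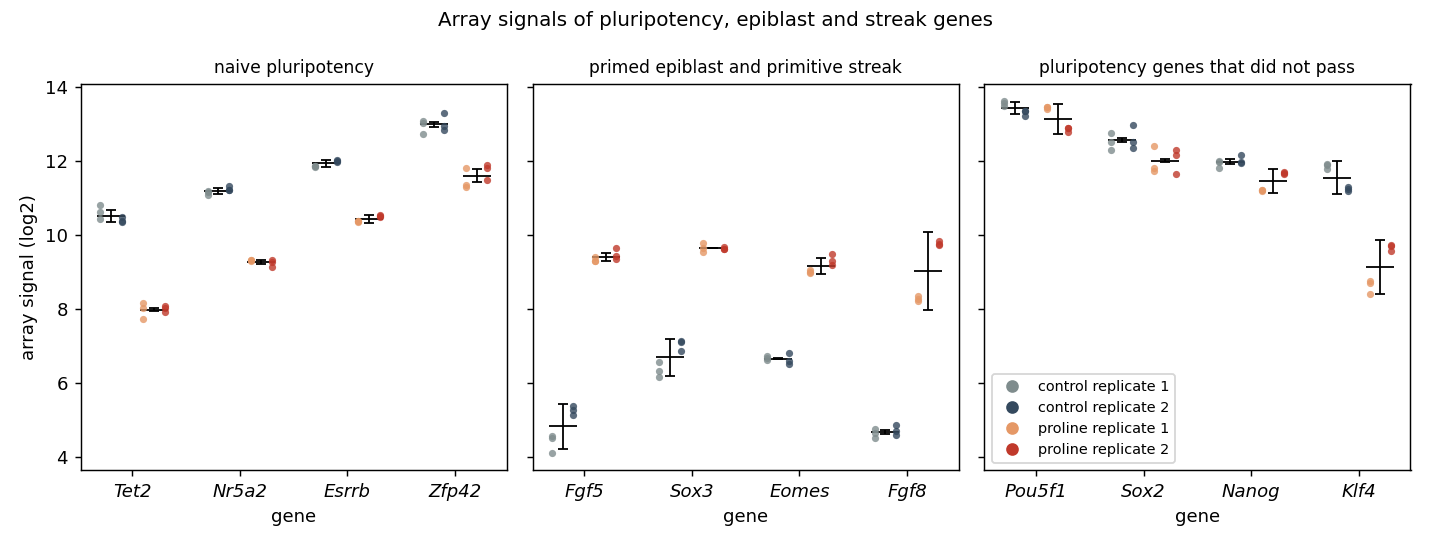
Log2 signals on each of the 12 arrays for 12 genes (points, arrays coloured by biological replicate; black bars, mean and SD of the 2 biological replicates of a group). Tet2, Nr5a2, Esrrb and Zfp42 fell, Fgf5, Sox3, Eomes and Fgf8 rose, and Pou5f1, Sox2, Nanog and Klf4 did not pass the test, Klf4 with a log2 fold change of -2.41.

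Genes of naive pluripotency, the state of the pre-implantation epiblast, were lower after proline. Of 22 measured, 10 fell, 0 rose and 12 did not pass, and 21 had a log2 fold change below 0. The falls included Tbx3 (-2.64 ± 0.42), the DNA demethylase Tet2 (-2.53 ± 0.13), Prdm14 (-1.96 ± 0.20), the nuclear receptors Nr5a2 (-1.93 ± 0.12) and Esrrb (-1.49 ± 0.13), and Zfp42 (-1.39 ± 0.14), which is also called Rex1. Klf4 measured -2.41 ± 0.41 (adjusted p = 0.0553) and Nanog -0.54 ± 0.19 (adjusted p = 0.201), and neither passed. Adjusted over the list alone, 19 members were lower and 0 higher. Camera placed the list below other genes (adjusted p = 8.60e-13), with an adjusted p = 2.83e-14 with an estimated correlation. Both compare genes with genes and do not measure the spread between biological replicates. Fry, which tested the list by itself, gave an adjusted p of 0.0180. In the same arrays poly-A spike-ins were lower by 0.42 and 18S ribosomal RNA by 1.35 in proline than in control (log2).

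General pluripotency genes, which naive and primed cells share, held 0 genes past the threshold among 13 measured in limma, with 4 at an unadjusted p under 0.05. Pou5f1, which encodes Oct4, measured -0.29 ± 0.23 (adjusted p = 0.569), Sox2 -0.55 ± 0.11 (adjusted p = 0.0776) and Lin28a 0.67 ± 0.11 (adjusted p = 0.0530). The count adjusted over the list alone was 1 higher and 1 lower. Camera did not separate this list from other genes (adjusted p = 0.281).

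Genes of the primed, post-implantation epiblast were higher after proline. Of 18 measured, 6 rose, 0 fell and 12 did not pass. Beside Fgf5, the transcription factor Sox3 rose by 2.95 ± 0.25, the cadherin Cdh2 by 2.45 ± 0.23 and the carbonic anhydrase Car14 by 2.39 ± 0.23 on the log2 scale, and Tead2 and Zic5 also rose. Otx2 (1.20 ± 0.22, adjusted p = 0.0618) and the de novo DNA methyltransferase Dnmt3b (1.10 ± 0.27, adjusted p = 0.105) did not pass. Adjusted over the list alone, 14 members were higher and 0 lower. The camera call (adjusted p = 2.41e-10) held at an adjusted p = 0.00472 with an estimated correlation. In fry, which tested the list by itself, the list did not pass (adjusted p = 0.185). Beta-actin 5' minus 3' was 0.25 higher in proline than in control arrays (log2), in the direction of this list.

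Primitive streak and mesendoderm genes were also higher as a list. Among 17 measured, 4 rose, 0 fell and 13 did not pass. With Fgf8, the follistatin gene Fst rose by 2.96 ± 0.24, the T-box factor Eomes by 2.51 ± 0.15 and Msx1 by 1.15 ± 0.13. Mixl1 measured 2.96 ± 0.51 (adjusted p = 0.0559). The list held 7 higher and 0 lower members adjusted over the list alone. Camera's adjusted p of 6.80e-05 became an adjusted p = 0.141 with an estimated correlation. The median of this list was 0.31 higher in proline replicate 2 than in proline replicate 1, and Fgf8 read 9.78 and 8.30 in them.

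Epithelial junction genes rose in 6 of 24 measured members, with 0 falls and 18 that did not pass. The increases were in the claudins Cldn7 and Cldn3 (1.92 ± 0.25), occludin (Ocln, 1.86 ± 0.11), the polarity gene Crb3 (1.60 ± 0.13), Epcam (1.25 ± 0.18) and Tjp3 (0.87 ± 0.14). E-cadherin (Cdh1) measured 0.48 ± 0.14 (adjusted p = 0.137). A count of 7 was higher adjusted over the list alone. The camera call (adjusted p = 4.44e-07) was lost at an adjusted p = 0.105 with an estimated correlation. The list median was also 0.15 higher in control replicate 2 than in control replicate 1 (18 of 24 above 0) and 0.31 higher in proline replicate 2 than in proline replicate 1 (20 of 24). Beta-actin 5' minus 3' was higher by 0.40 and 0.42 in these pairs, and the median over the 4 proline minus control pairs ran from 0.32 to 1.46.

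Mesenchymal transition genes did not shift together. Of 24 measured, Cdh2 and Twist1 (1.24 ± 0.13) rose, 0 fell and 22 did not pass. The secreted matrix gene Tgfbi measured -3.08 ± 0.55 (adjusted p = 0.0604), Zeb1 -1.65 ± 0.30 (adjusted p = 0.0605), vimentin (Vim) -0.19 ± 0.49 (adjusted p = 0.882) and Snai1 0.36 ± 0.32 (adjusted p = 0.615). Adjusted over the list alone, 3 were higher and 2 lower, and camera's adjusted p was 0.471, or 0.0124 in the higher direction without proline replicate 1.

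Actin cytoskeleton genes and targets of serum response factor (SRF) were higher as a list. Among 28 measured, 3 rose: the matricellular gene Ccn1 (3.15 ± 0.47), zyxin (Zyx, 2.48 ± 0.32) and tropomyosin Tpm2 (1.23 ± 0.19). The other 25 did not pass, and 9 members were higher adjusted over the list alone. Camera gave an adjusted p of 1.72e-05, against an adjusted p = 0.423 with an estimated correlation. Without proline replicate 2 the camera adjusted p was 0.0527 and the list's median log2 fold change 0.24 in place of 0.73. The list median was also 0.44 higher in control replicate 2 than in control replicate 1 and 0.66 higher in proline replicate 2 than in proline replicate 1, and beta-actin 5' minus 3' was higher by 0.40 and 0.42 in the same pairs.

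LIF and STAT3 target genes were lower as a list although LIF was present in both groups. Of 15 measured, Gbx2 (-2.52 ± 0.28), the LIF receptor gene Lifr (-1.70 ± 0.23) and Bcl3 (-1.25 ± 0.19) fell, Junb rose (0.80 ± 0.11) and 11 did not pass. Klf4, Klf5, Tfcp2l1 and Socs3 of this list are also in the naive list. Of the 15, 7 were lower and 1 higher adjusted over the list alone. Camera's adjusted p of 0.0201 became an adjusted p = 0.423 with an estimated correlation, 0.0740 without proline replicate 1 and 0.0552 with the median over probe sets.

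Among genes of Nodal and BMP signalling, 15 were measured. Lefty2 (1.31 ± 0.19) and the activin receptor Acvr2b (0.98 ± 0.15) rose, Inhbb fell and 12 did not pass. The median of this list was 0.35 and its mean -0.04, the one above and the other below 0, because of Inhbb. Camera gave an adjusted p of 0.229 in the higher direction, fry put it in the lower direction, and 3 members were higher and 1 lower adjusted over the list alone. Canonical Wnt targets held 16 measured genes, of which the feedback genes Axin2 (1.26 ± 0.13) and Nkd2 (0.82 ± 0.13) rose, the Wnt deacylase Notum fell (-2.40 ± 0.12) and 13 did not pass. Sp5 measured 3.30 ± 0.91 (adjusted p = 0.132). The counts were the same adjusted over the list alone, and camera's adjusted p was 0.144, or 0.0447 without control replicate 2.

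**Figure D3:**
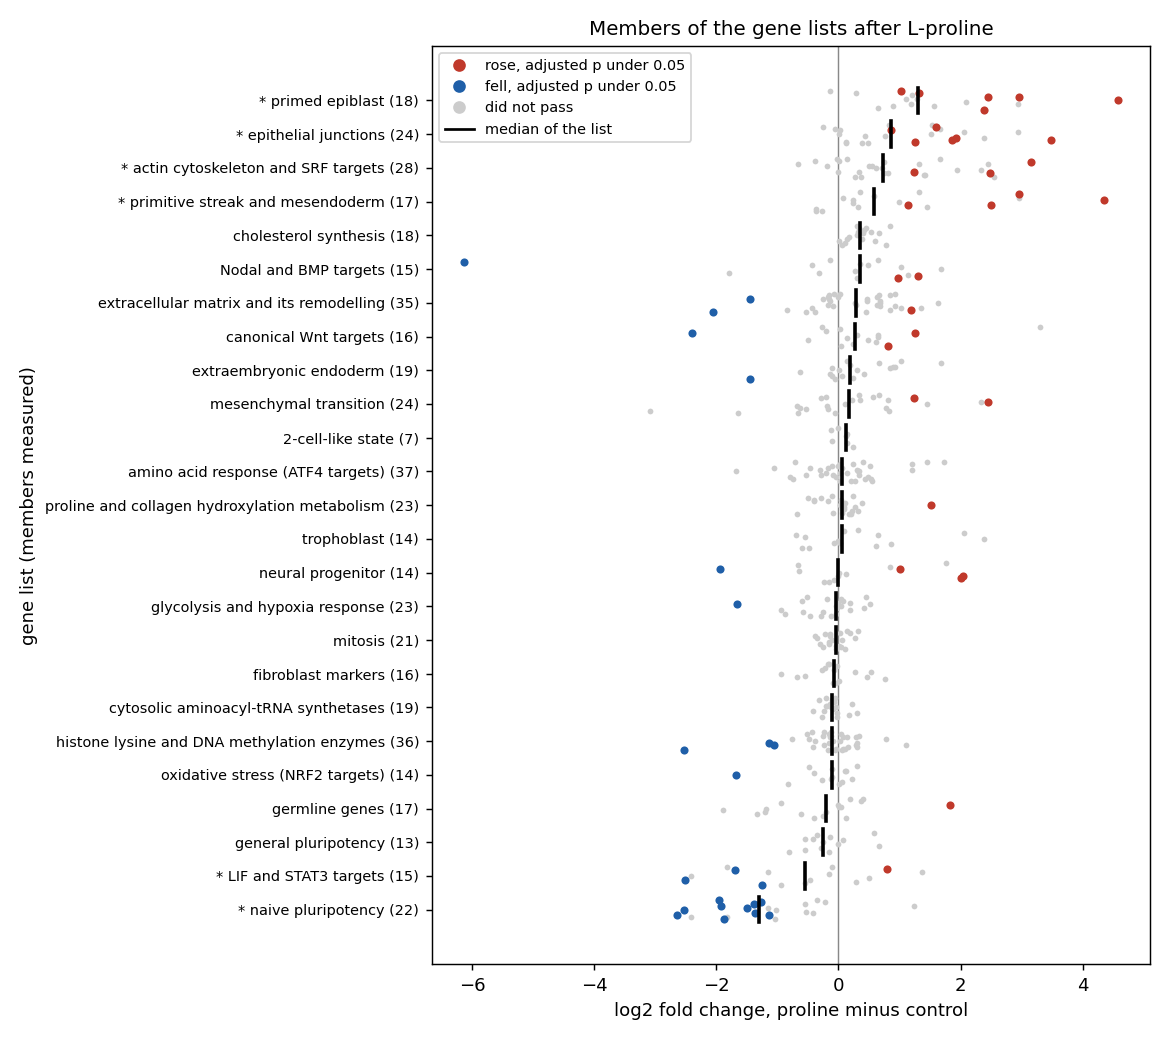
Log2 fold changes, proline minus control, of the measured members of the 25 gene lists (points, genes; red, rose; blue, fell; grey, did not pass; black bars, list medians; asterisks, lists with a camera adjusted p under 0.05). The naive list had a median of -1.31 and the primed epiblast list a median of 1.30.

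Lists tied to the amino acid itself did not pass in camera with all replicates. Amino acid response genes (ATF4 targets) held 0 genes past the threshold among 37 measured, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05 in limma. The median of this list was -0.53 in control replicate 2 minus control replicate 1, with 32 of 37 below 0. Over the 4 proline minus control pairs it ran from -0.26 to 0.57. With controls this far apart, the absence of calls does not show that these genes were unaffected. Asparagine synthetase (Asns) measured -0.09 ± 0.21 and Atf4 -0.30 ± 0.19, and camera's adjusted p was 0.529, or 0.0130 in the higher direction without control replicate 1. In proline metabolism and collagen hydroxylation, the prolyl 3-hydroxylase gene P3h2 rose by 1.51 ± 0.17 and 22 of 23 measured did not pass, with 1 higher adjusted over the list alone. Proline dehydrogenase (Prodh) measured -0.29 ± 0.28 and the proline synthesis gene Aldh18a1 0.21 ± 0.30, with a camera adjusted p of 0.654. Cytosolic aminoacyl-tRNA synthetases held 0 genes past the threshold among 19, 0 over the list alone and 1 at an unadjusted p under 0.05, with a camera adjusted p of 0.372. The proline-charging enzyme gene Eprs measured -0.24 ± 0.15.

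Extracellular matrix genes went both ways, and the 2 proline replicates differed. Against control replicates 1 and 2, the list median was -0.01 and -0.005 in proline replicate 1. In proline replicate 2 it was 0.62 and 0.60, with 25 of 35 above 0 in each pair. Of 35 measured, the gelatinase gene Mmp2 rose (1.19 ± 0.15), the basement membrane genes Nid1 (-2.05 ± 0.21) and Lama1 (-1.45 ± 0.22) fell, and 32 did not pass. Adjusted over the list alone, 5 were higher and 3 lower, and the camera adjusted p of 0.223 became 5.85e-05 in the higher direction without proline replicate 1. Histone lysine and DNA methylation enzymes held 36 measured genes, of which Tet2, Tet1 (-1.14 ± 0.14) and the histone demethylase Kdm3a (-1.05 ± 0.11) fell and 33 did not pass. Kdm4c measured 0.05 ± 0.15, 4 members were lower adjusted over the list alone, and camera's adjusted p was 0.229.

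Markers of other cell types moved as single genes. Neural progenitor genes included 3 that rose, Zfp521 (2.03 ± 0.16), nestin (Nes, adjusted p = 0.0352) and Fabp7 (1.01 ± 0.16), 1 that fell, the neuronal tubulin Tubb3 (-1.94 ± 0.24), and 10 that did not pass, with 4 higher and 1 lower adjusted over the list alone. This list's median was -0.001, its mean 0.29 and its camera adjusted p 0.422 in the higher direction. In extraembryonic endoderm, Lama1 fell and 18 of 19 did not pass, among them Dab2 (1.68 ± 0.28, adjusted p = 0.0545). Adjusted over the list alone 4 were higher and 2 lower, and the camera adjusted p of 0.144 was 0.0482 without control replicate 2 and 0.0415 without proline replicate 1. Trophoblast and fibroblast markers held 0 genes past the threshold among 14 and 16 measured, also adjusted over each list alone, with 3 and 2 at an unadjusted p under 0.05. Cdx2 measured 0.65 ± 0.26 and Col1a1 -0.08 ± 0.43, and both lists had a camera adjusted p of 0.968. Fry gave the opposite direction to camera for both.

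Of the remaining lists, germline genes included 1 that rose, Sycp3 of the synaptonemal complex (1.82 ± 0.25), and 16 that did not pass, among them Dazl (-1.21 ± 0.30), with 1 higher adjusted over the list alone and a camera adjusted p of 0.484, or 0.0478 in the lower direction without control replicate 2. Glycolysis and hypoxia genes held 1 fall among 23, in the phosphofructokinase gene Pfkp (-1.65 ± 0.22), the only one also adjusted over the list alone. Their camera adjusted p of 0.459 was 0.0260 without control replicate 2 and 0.0119 without proline replicate 2, both in the lower direction. Targets of NRF2, the oxidative stress regulator, held 1 fall among 14, in the quinone reductase gene Nqo1 (-1.68 ± 0.12), again 1 over the list alone, with a camera adjusted p of 0.229. Cholesterol synthesis genes were all above 0 in log2 fold change, 18 of 18, mainly through proline replicate 2. Replicate 2 was higher in both groups, by a median of 0.29 in controls (16 of 18 above 0) and 1.16 after proline (18 of 18). Against control replicates 1 and 2, proline replicate 1 had medians of -0.02 and -0.32, with 9 and 16 of 18 below 0, and proline replicate 2 had 0 below 0. In limma 0 passed, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Their camera adjusted p of 0.0976 was 0.0234 without control replicate 2, 2.41e-09 without proline replicate 1, 0.0493 with the median over probe sets and 0.0357 with the random block on the 12 arrays, and Cyp51 read 9.94 in proline replicate 2 against 8.78 in proline replicate 1. Mitosis genes, 21 in number, and genes of the 2-cell-like state, 7 in number, held 0 past the threshold and 0 adjusted over each list alone, with 1 and 0 at an unadjusted p under 0.05, and camera adjusted p of 0.619 and 0.640. Bub1b measured -0.34 ± 0.12 and Tcstv1 -0.11 ± 0.12.

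In all, camera put 6 of the 25 lists past the threshold, 4 higher and 2 lower, and 2 of these held with an estimated correlation. Fry found 1 list moved in one direction, naive pluripotency (adjusted p = 0.0180), and 16 lists with changes in either direction.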

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

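In 260 groups of 6 arrays, 1 array stood apart from the other 5 in 4 groups, where chance sets apart about 1 in 20 groups of independent arrays. The arrays here are 3 repeats of each of 2 biological replicates, so that rate need not hold for them. Fgf5 read 9.652 in proline array 2b, against 9.306 to 9.429 in the other proline arrays. Nr5a2 read 9.141 in proline array 2c, against 9.270 to 9.325. Ascl2, a trophoblast gene, read 5.984 in proline array 2c, against 6.372 to 6.438. Tcstv1, a gene of the 2-cell-like state, read 2.665 in proline array 2b, against 2.896 to 3.025. The 4 values lie on 2 arrays of proline replicate 2, and each value was averaged with those of the other 2 arrays of that replicate. Among 10092 probe sets with no gene name or several, which entered no count of genes, 5 passed the threshold when every probe set was tested by itself, 4 higher and 1 lower after proline.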

How the results depend on the processing

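All alternatives here were fixed before the data were examined. The count of 794 genes was 748 to 937 under quantile normalization, median centring, the filter on dim genes and the intensity trend, and 720, 777, 726 and 720 of the same genes were called in them. It was 351 with the median over probe sets and 45 with every probe set tested. In the latter, 7951 probe sets were at an unadjusted p under 0.05 in limma and more tests were adjusted for. Why fewer passed there was not tested. With 12 independent arrays the count was 6804 and with a random block 3987 (consensus correlation 0.548). Arrays of different groups with the same replicate number deviated together (median r = 0.20 across genes, 0.08 to 0.38). Arrays with the other number gave -0.20, which only mirrors this value, since deviations were taken from means of 2 replicates. The 2 pairs do not settle whether the numbers pair the samples. With the replicate block on the 4 means 2039 genes were called, and on the 12 arrays 8334. The count of at least 2-fold changes, 619, was 312, 45, 1255, 1248, 1113 and 1259 in the same order, and 794 at 1.5-fold. Leaving out replicates or arrays gave 0 to 844 genes and 0 to 671 at least 2-fold, with 0 for each of the 4 biological replicates, where 1 sample stands for its group and is assumed to vary like the other, and 732 to 844 for single arrays. The share of higher genes was 69.4%, 65.9% and 69.4% as deposited, with quantile normalization and with median centring, and 52.5%, 58.1%, 62.9%, 50.3% and 55.6% with independent arrays, the random block, the block on the 4 means, the block on 12 arrays and every probe set. Both replicate blocks brought cholesterol synthesis past the threshold in the higher direction (camera adjusted p = 0.00267 and 0.00196) and changed no other list's call. The 6 lists became 2 with an estimated correlation and 1 with fry, and 6 to 11 when a replicate or array was left out. No direction was reversed among the 56 named genes past the threshold, wherever they were tested in 25 settings. Without each biological replicate 0 of the 56 passed, with the median over probe sets 19 no longer did, and in the other settings 0 to 5 of those tested. Of the 123 named genes, those that passed only in an alternative numbered 20 and 58 with the replicate block on the 4 means and the 12 arrays, 38 with the random block, 54 with independent arrays, 9 with the intensity trend and 0 to 5 in the other settings. The pseudocounts listed for linear values were not run, since the values are log2. Signal near background limits the genes under the 40th percentile.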

Other observations

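The gene families, the immediate early list and its part in no other list, the test of handling or serum, the pairs of biological replicates, the test of RNA quality for the difference between replicates and the bootstrap intervals of medians were chosen after results had been seen, and the bounds of the other tests in this part were written before their values. Gene families were formed from symbols sharing a stem with at least 10 measured members, and 235 of them were tested with camera. Frizzled receptors, which bind Wnt ligands, were higher as a family: of 11 genes with the stem Fzd, 1 of them the antisense transcript Fzd10os, 4 rose, Fzd2 (2.68 ± 0.37), Fzd8 (1.68 ± 0.17), Fzd1 (1.10 ± 0.16) and Fzd6 (1.06 ± 0.13), while Fzd5 fell (-1.40 ± 0.11). Among 24 Dusp genes, dual-specificity phosphatases that include inhibitors of MAP kinases, Dusp6 (1.06 ± 0.15), Dusp1 (0.87 ± 0.13) and Dusp3 (0.85 ± 0.11) rose and Dusp27 fell (-1.91 ± 0.14). The Lrp stem, which holds Wnt co-receptors and lipoprotein receptors, had 1 rise among 12, Lrp4 (0.93 ± 0.13), and the Rassf stem 2 among 10, Rassf6 (1.39 ± 0.12) and Rassf2 (1.08 ± 0.14). Camera adjusted p was 0.0251, 0.0322, 0.0322 and 0.0380 for Fzd, Dusp, Lrp and Rassf, and adjusted p = 0.0244, 0.0244, 0.0381 and 0.0398 with an estimated correlation. Adamts proteases were higher (adjusted p = 0.0322, or adjusted p = 0.486 with an estimated correlation), with rises in Adamts15 (2.61 ± 0.28) and Adamts6 (0.95 ± 0.12). RNA polymerase subunits (Polr, median -0.31) and DEAD-box helicases (Ddx, median -0.24) were lower, both at an adjusted p of 0.0251, with 0 genes past the threshold in limma and 5 of 25 and 12 of 35 at an unadjusted p under 0.05. With an estimated correlation their adjusted p = 0.430 and 0.475. The 7 directions were the same under quantile normalization and median centring.

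Immediate early genes, a list of 20 written after the SRF list had been seen and with some members' values already known, had a median of 0.97 and a camera p of 2.41e-06, or p = 2.69e-07 with an estimated correlation. These p describe a list partly chosen on the pattern. The 14 members in none of the 25 fixed lists had a median of 0.88, with 11 above 0 and 3 that rose (camera p = 0.000341, or p = 0.00014 with an estimated correlation). Jun (2.89 ± 0.39), Klf6 (1.91 ± 0.20), Junb, Dusp1 and Ccn1 rose, 0 fell and 15 did not pass, among them Fos (1.38 ± 0.60, adjusted p = 0.283) and Egr1 (1.05 ± 0.44, adjusted p = 0.266). Some of these read higher mainly in proline replicate 1: Fos 9.64 against 8.02 in proline replicate 2 (controls 7.84 and 7.07), Egr1 11.465 against 10.18 (controls 9.75 and 9.81), Fosb 6.01 against 4.0 (controls 3.98 and 3.95) and Egr2 5.38 against 4.04 (controls 3.94 and 3.90). The SRF list ran the other way, with a median 0.66 higher in proline replicate 2.

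The fall of naive and the rise of primed epiblast genes were set against RNA quality and RNA input, since beta-actin 5' minus 3' was higher and poly-A spike-ins were lower after proline. In proline replicate 1 against control replicate 2 the actin difference runs the other way (-0.16) and the spike-ins differ by 0.03. In that pair the naive list still had a median of -1.21 (bootstrap interval -1.60 to -0.74, 21 of 22 below 0) and the primed list one of 1.25 (1.01 to 1.95, 17 of 18 above 0), which argues against both as the whole cause. Over all 4 proline minus control pairs the naive median was -1.44 to -1.21 and the primed median 1.18 to 1.63, against -0.12 and 0.013 (naive) and 0.57 and -0.07 (primed) between replicates of one group. In that first pair, 18S ribosomal RNA still read 9.74 in proline replicate 1 and 10.04 in control replicate 2. An effect of proline on the cell state, which the design names, stays a hypothesis. The lists were fixed beforehand, but their shifts were seen and set against other causes in the same data. Each group held 2 biological replicates. A partial role of RNA quality or input, and other differences between the cultures, were not tested.

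Biological replicate 2 of both groups lay toward the proline side. Across genes, which are not independent replicates, control 2 minus control 1 correlated with the proline effect at r = 0.387, and proline 2 minus proline 1 at r = 0.261. The proline effect is made from the same biological replicates. A larger deviation of control replicate 1 or proline replicate 2 than of its partner would by itself raise these r. Beta-actin 5' minus 3' was higher in replicate 2 by at least 0.40 in each group, which was seen before RNA quality was considered and so leaves that explanation open without bearing it out. Whether the replicates differ in how far cells had left the naive state also stays open. The naive median was -0.12 in the control pair (interval -0.28 to 0.10) and 0.013 in the proline pair (-0.12 to 0.20), and the primed median 0.57 (-0.02 to 0.78, 13 of 18 above 0) and -0.07 (-0.50 to 0.14, 11 of 18 below 0).

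The higher SRF targets and immediate early genes share Ccn1 and Ccn2. A response to handling or serum at harvest stays open and untested by independent genes, since the immediate early list, with a median of 0.97 (0.72 to 1.05 in the 4 proline minus control pairs), was partly chosen on the pattern. Signalling started by proline would give the same values. Dependence on 1 biological replicate is not settled for the SRF list, whose median was 0.24 without proline replicate 2 (interval -0.02 to 1.09) and 0.65 to 1.32 without each of the others. By the bounds set beforehand, without intervals, differing progress out of the naive state would have counted as excluded for the replicate difference, and dependence on 1 replicate as met for the SRF list.

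Of the 3 splits of the 4 biological replicates into 2 and 2, 1 called as many as 794 genes, the real one, and the highest of the other splits called 0 in limma, with 564 and 103 genes at an unadjusted p under 0.05 against 4015 in the real one. In the other splits each group holds 1 control and 1 proline replicate, so a difference between control and proline counts as spread within the groups. Such splits call few genes whatever caused that difference, so their counts do not bear on its cause. With 3 splits, a share under 0.05 cannot be reached.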
